A study of Mus musculus with 6 samples.

How the data were processed

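Gene expression was measured by RNA sequencing in 6 mouse samples, 2 in each of 3 groups, which the submitters code as IG, NG and TG. Per the labels, the cells were spinal cord neurons from ICR mice, an outbred stock, at postnatal day 3, kept in DMEM, a standard culture medium. The labels give IG as untreated control, NG as mechanically injured, and TG as mechanically injured and then incubated with 75% hydrogen. RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. Nothing in the labels says that the samples of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

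Bowtie2 2.0.6, HTSeq 0.6.1 and the mm10 genome are named in the submitters' processing notes. The gene annotation, the counting settings, and the tool behind the fold changes and p-values are not given in the sources used here. The authors deposited 3 tables of 35275 Ensembl genes, one for each pair of groups. Per the file headers, each holds a read count column for each group of the pair, a log2 fold change, a p-value and an adjusted p-value. The deposited count columns are not whole numbers. As deposited, this signal had been normalised by the authors and averaged, as the mean over the 2 libraries of a group of reads divided by a size factor, and the factors belong to the 4 libraries of that table. In the deposited tables the log2 fold change was the log2 of the ratio of these means, given as IG over NG, TG over IG and TG over NG. The authors' adjusted p-value equalled a Benjamini-Hochberg adjustment of the deposited p-value to within 2.3e-05, and the genes marked significant were those with a value under 0.05.

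Each group stands in 2 of the deposited tables with different size factors. The pair of means of a gene therefore gives 2 equations for the reads of the gene in the 2 libraries. Solved this way, 100% of the 35275 genes of each group gave whole, non-negative reads in both libraries, within a tolerance of 0.001 reads. The largest distance from a whole number was 1.0e-05. Median-of-ratios size factors computed from the recovered reads of each table's 4 libraries equalled those in the deposited means up to rounding error. In simulated libraries the same procedure returned the reads of both libraries for at least 35273 of 35275 genes. The deposited means carry no sample numbers, so the libraries of a group are called A, the deeper, and B, the shallower. Reads assigned to genes were 23516544 and 15749447 in IG A and B, 20069421 and 15920819 in NG A and B, and 23911141 and 16790032 in TG A and B.

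The 2 libraries of a group differed by more than sampling noise. Over genes with at least 50 reads, the chi-square statistic per gene was 8.94 in IG, 17.3 in NG and 5.40 in TG, so the 2 are not one library divided by chance, though separate preparations of one RNA would also differ by more than sampling noise. On the log2 scale, Pearson's r across genes between the libraries of a group was 0.987 to 0.989. The difference of the deeper from the shallower library was shared in part between groups, with correlations across genes of 0.461 for IG and NG, 0.287 for IG and TG and 0.309 for NG and TG.

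The files hold means, not the counts that the plan had assumed. For files with only group means, the plan was to fit no model and to count the authors' own adjusted p under 0.05. Since the reads per library could be recovered, the test planned for normalised values was run on them instead, which was not part of the plan for such files. limma 3.58.1 in R 4.3.3 was run on log2 of normalised reads plus a pseudocount of 1, with all 6 libraries in one fit and 24511 genes with a read in any library. The recovered reads were scaled by median-of-ratios factors over the 6 libraries. The scaling and the trend of the prior variance on the mean level were not part of the plan. There were 3 residual and 5.23 prior degrees of freedom. Calls used a two-sided test and a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. The counts of the authors' deposited table stand beside these calls. In data simulated from the real means and library sizes, with 200 changed genes among about 23750, the fit recovered 41.8% of genes changed by 1.5-fold, 71.6% of those changed by 2-fold and 89.4% of those changed by 4-fold for NG against IG, and 2.61% of its calls were false. For TG against NG these values were 41.8%, 79.1%, 95.5% and 3.01%, and for TG against IG 35.8%, 74.6%, 97.0% and 2.42%.

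Gene symbols and positions come from the GENCODE M21 annotation of mm10. A symbol was found for 34490 of the 35275 gene IDs and for 98.8% of those with a read. Before the data were examined, 32 gene lists were fixed, 12 of cell type markers and 20 of pathways. Each was tested with camera at a preset correlation of 0.01, on the log2 normalised reads, with adjustment over the lists. The plan had given log2 CPM for this step. An estimated correlation and the fry test were run beside it. In simulated data camera with the preset correlation called 5 of 5 moved lists and 0 of 20 others in each comparison, while with an estimated correlation it called 0 of the 5 moved lists. The simulated genes varied independently, so false calls for lists whose genes move together were not tested. fry asks whether the genes of a list move on balance one way, and does not compare them with other genes. A further 9 lists were written after the genes with the largest changes had been seen: hepatocytes (2 lists), adipocytes (2 lists), skeletal muscle (a second list), smooth muscle cells, lung epithelium, adrenal cortex and dorsal root ganglion neurons. Members of the second lists and of the dorsal root ganglion list were chosen without their values having been looked at.

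Named genes follow a rule set before the data were examined. For each comparison these are the 5 called genes with the highest and the 5 with the lowest log2 fold change that have a symbol other than a Gm, Rik or LOC name, at least 10 CPM in the higher group and no overlap between libraries. Added to these, from each fixed list with 2 or more called members, are up to 3 called members with the smallest adjusted p. CPM is the usual scaling of the reads of a gene by all reads of its library assigned to genes, computed from the recovered reads. A gene withheld for evaluation is not reported here. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group. Printed folds of genes with under 10 reads in the lower group carry a 95% exact binomial interval. Intervals and bounds cover counting error alone, since reads without molecular identifiers are not independent molecules. The chance value for opposing changes came from 100 simulations of unchanged groups that share libraries, over as many genes as were called, picked in each simulation by the difference of NG from IG over its spread.

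Alternatives were other pseudocounts, a filter on low values, trimmed mean of M-values, upper quartile and total read scaling, no trend in the prior variance, voom weights, a term for the deeper or shallower library, a correction for transcript GC content and length, fits of only the groups compared, and leaving out each library in turn. In simulated data the correction removed every one of 4652 to 4918 calls made by an added GC trend. That trend used the same GC values that the correction fits, and no length trend was added. The simulation therefore checks only that the step runs as intended, not how well it removes bias in the real libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.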

Results

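Transcript levels were compared between 3 groups of mouse spinal cord neuron samples, each with 2 RNA-seq libraries. IG is labelled as untreated control, NG as mechanically injured, and TG as mechanically injured and incubated with hydrogen, a gas studied as an antioxidant. The group codes are used throughout. Each library held 15749447 to 23911141 reads assigned to genes, and 20630 to 21270 genes had a read. Levels are normalised reads, given as mean ± SD (n = 2 libraries per group). On the log2 scale, Pearson's r across genes was 0.987 or more within groups. It was 0.952 to 0.955 between IG and TG libraries, 0.870 to 0.877 between IG and NG, and 0.856 to 0.861 between NG and TG. The first principal component held 72.6% of the variance and set NG apart from both other groups. The second held 21.2% and separated IG from TG. Myelin basic protein transcripts of Mbp made up 4.08% to 7.34% of the reads of a library, and globin transcripts 1.48% to 2.19%. Mitochondrially encoded transcripts made up 17.2% and 14.2% of reads in NG A and B, against 4.66% to 5.64% in the libraries of IG and TG.

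The comparison of NG with IG asks what mechanical injury changed, as the groups are labelled. The lists of immediate early genes, inflammatory cytokines, general neuron markers, spinal excitatory and inhibitory neurons, synaptic vesicles and the oligodendrocyte lineage were lower in NG, labelled injured, than in IG, labelled control. That of motor and cholinergic neurons was not called. Genes of muscle, connective tissue, blood vessels, the cell cycle and the phagocyte NADPH oxidase were higher in NG. Fosb, an activity-induced transcription factor gene, stood at 173 ± 0.472 in NG and 1665 ± 101 in IG (log2 fold change -3.26, SE 0.09, limma adjusted p = 2.7e-07). The cytokine gene Il6 stood at 2.18 ± 0.330 in NG and 231 ± 5.30 in IG (log2 fold change -6.19, SE 0.23, limma adjusted p = 9.8e-07), lower in NG by 107-fold with a counting interval of 41.5 to 394. The skeletal muscle troponin gene Tnnt3 stood at 14600 ± 329 in NG and 1378 ± 69.7 in IG (log2 fold change 3.41, SE 0.07, limma adjusted p = 1e-07).

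Of the 14 immediate early genes, which respond within minutes to activity or stress, 13 fell in NG and 1 did not pass the test, with a median log2 fold change of -1.54 (14 fell when adjusted over the list alone). The list was called lower (camera adjusted p = 8.27e-08, and adjusted p = 0.186 with an estimated correlation). Fos changed by -1.93 and Nr4a1 by -2.35 on the log2 scale. Among 15 inflammatory cytokines and NF-kB targets, 13 fell and 2 did not pass (14 fell when adjusted over the list alone). Their median was -2.82 (camera adjusted p = 8.27e-08, and adjusted p = 0.0944 with an estimated correlation). The chemokine genes Ccl2 and Cxcl1 had log2 fold changes of -3.52 and -5.40. Of 10 axon injury and regeneration genes 7 fell and none rose (8 fell when adjusted over the list alone; camera adjusted p = 0.00433, and adjusted p = 0.12 with an estimated correlation). Atf3, a transcription factor induced in injured neurons, stood at 104 ± 17.7 in NG and 1065 ± 23.2 in IG (log2 fold change -3.35, SE 0.12, limma adjusted p = 9.6e-07). Sprr1a, also induced by axon injury, had 2 reads in NG and was lower there by 40.1-fold with a counting interval of 10.8 to 336. In the heat shock list 6 of 10 members fell and 1 rose (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.122 with an estimated correlation), and the inducible chaperone gene Hspa1a changed by -4.38. Of 8 reactive astrocyte genes 5 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.299 with an estimated correlation). Serpina3n, a marker of astrocyte activation, stood at 216 ± 3.73 in NG and 1532 ± 73.9 in IG. The call of that list was lost in 5 of the 6 fits without 1 library (all but the one without TG A), after GC and length correction and with the filter on low values. Its median was -0.85, and -0.73 to -0.96 where the call was lost.

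Of 16 general neuron markers 15 fell in NG and none rose (16 fell when adjusted over the list alone), with a median of -0.86 (camera adjusted p = 1.84e-06, and adjusted p = 0.0944 with an estimated correlation). The neurofilament gene Nefh stood at 3656 ± 25.2 in NG and 8524 ± 75.7 in IG (log2 fold change -1.22, SE 0.07). Among 10 genes of spinal excitatory and inhibitory neurons 8 fell and 1 rose, also when adjusted over the list alone (median -1.27; camera adjusted p = 5.57e-04, and adjusted p = 0.107 with an estimated correlation). Slc6a5, the glycine transporter of inhibitory neurons, stood at 668 ± 61.6 in NG and 3155 ± 76.4 in IG (log2 fold change -2.24, SE 0.08, limma adjusted p = 1.1e-06). Synaptic vesicle genes fell in 11 of 12 cases, also when adjusted over the list alone (median -0.98; camera adjusted p = 2.46e-05, and adjusted p = 0.109 with an estimated correlation). All 14 genes for glutamate receptors and voltage-gated channels fell by either adjustment, among them Cacna1b and Scn8a, with a list median of -1.36 (camera adjusted p = 1.22e-07, and adjusted p = 0.0944 with an estimated correlation). In the oligodendrocyte list 9 of 12 members fell and none rose (10 fell when adjusted over the list alone; median -1.06; camera adjusted p = 2.88e-05, and adjusted p = 0.107 with an estimated correlation). Mag, a myelin glycoprotein gene, stood at 8467 ± 888 in NG and 30660 ± 1700 in IG. Astrocyte markers fell in 8 of 12 cases and rose in 2, also when adjusted over the list alone (camera adjusted p = 0.0438, and adjusted p = 0.186 with an estimated correlation), a call lost in each of the 6 fits without 1 library, with upper quartile scaling and with the filter on low values. The median of the astrocyte list was -0.44, and -0.40 to -0.48 where the call was lost. Of 12 proteoglycan genes of the glial scar 8 fell and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.107 with an estimated correlation), and the tenascin gene Tnr changed by -2.99. That list's call was lost after GC and length correction, where its median was -0.75 against -1.095 without it. Cholesterol synthesis genes fell in 11 of 12 cases, also when adjusted over the list alone (median -0.48; camera adjusted p = 1.48e-04, and adjusted p = 0.107 with an estimated correlation), with Sqle at -1.23.

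Markers of other cell types moved with these groups. Skeletal muscle genes rose in NG in 6 of 7 cases, also when adjusted over the list alone, with a median of 2.64 (camera adjusted p = 7.77e-05, and adjusted p = 0.107 with an estimated correlation). The muscle actin gene Acta1 stood at 39450 ± 3536 in NG and 4203 ± 277 in IG. Fibroblast and meningeal markers rose in 10 of 12 cases and fell in 2 by either adjustment, over all genes or adjusted over the list alone (median 1.21; camera adjusted p = 4.18e-04, and adjusted p = 0.107 with an estimated correlation), with the collagen gene Col1a2 at 31850 ± 108 in NG and 9629 ± 238 in IG. Endothelial markers rose in 7 of 9 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.00657, and adjusted p = 0.12 with an estimated correlation). All 12 cell cycle genes rose by either adjustment (median 1.49; camera adjusted p = 1.65e-07, and adjusted p = 0.0944 with an estimated correlation), with Ccna2, a cyclin of S and G2 phase, at 738 ± 20.6 in NG and 225 ± 7.55 in IG. All 7 NADPH oxidase genes, whose products make superoxide in phagocytes, also rose by either adjustment (camera adjusted p = 4.01e-05, and adjusted p = 0.107 with an estimated correlation), with Cybb at 1.83. Beside them, 5 of 14 microglia and macrophage markers rose and 2 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.448, and adjusted p = 0.494 with an estimated correlation). Ptprc, a marker of all leukocytes, stood at 947 ± 159 in NG and 351 ± 3.85 in IG (log2 fold change 1.42, SE 0.13, limma adjusted p = 5.2e-05). Of 12 interferon-stimulated genes 8 rose and 1, the chemokine gene Cxcl10, fell (11 and 1 when adjusted over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.12 with an estimated correlation). Mitochondrially encoded genes rose in 12 of 13 cases, also when adjusted over the list alone (median 1.71; camera adjusted p = 5.18e-06, and adjusted p = 0.189 with an estimated correlation). Of 18 nuclear genes of oxidative phosphorylation 9 rose and none fell, also when adjusted over the list alone (median 0.28; camera adjusted p = 0.0141, and adjusted p = 0.122 with an estimated correlation). After GC and length correction that median was -0.07 and the call was lost.

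**Figure D1:**
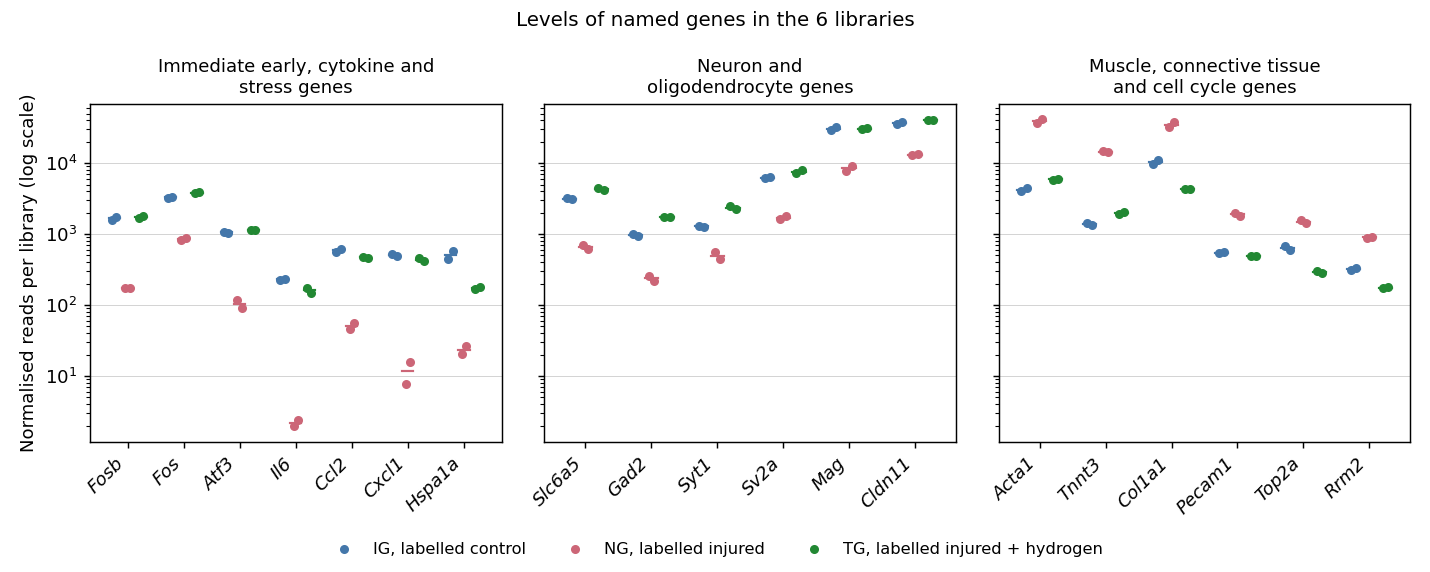
Normalised reads (log scale) of named genes in each library, with 1 point per library (A left, B right) and a bar at the mean of the group. In the left and middle panels both NG libraries lie below the IG and TG libraries for every gene drawn, with Fosb at 173 in NG against 1665 in IG and 1731 in TG, and in the right panel both NG libraries lie above them.

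The 5 highest named genes in NG were Rpl17-ps5, Retn, Adig, Sost and Cfd. Rpl17-ps5, a ribosomal protein pseudogene (chromosome 5, 22612628 to 22613182, mm10), had 0 reads in IG and 2367 ± 194 in NG, at least 1690-fold higher. Its level is uncertain, since near-identical copies can share reads. Cfd, the adipocyte gene of complement factor D (chromosome 10, 79890853 to 79892655), stood at 3205 ± 38.6 in NG and 30.8 ± 4.08 in IG. Retn, the fat cell hormone resistin, had 1 read in IG and was higher in NG by 460-fold with a counting interval of 82.1 to 18200. The 5 lowest were Mat1a, Hpx, Apob, Fgb and Fga, all genes of high expression in liver. Fgb, a fibrinogen chain gene (chromosome 3, 83040141 to 83049863), stood at 2.18 ± 0.330 in NG and 1238 ± 44.7 in IG, lower in NG by 578-fold with a counting interval of 226 to 2120. Mat1a, the methionine adenosyltransferase of liver, had 1 read in NG and was lower there by 1450-fold with a counting interval of 261 to 57500.

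Lists without a call in NG against IG, by camera with the preset correlation, were those of motor and cholinergic neurons (3 of 7 fell, as they did when adjusted over the list alone), microglia and macrophages (5 rose, 2 fell of 14), Schwann cells (5 of 8 fell, 1 rose), ependymal cells (4 of 6 fell, 1 rose), red blood cells (1 rose, 1 fell of 6), Nrf2 and antioxidant genes (4 rose, 3 fell of 14), apoptosis and p53 targets (5 rose, 4 fell of 14), endoplasmic reticulum stress (4 rose, 3 fell of 12), hypoxia and glycolysis (3 rose, 6 fell of 15), autophagy and lysosome (5 of 12 fell) and the mRNA methylation machinery (1 rose, 2 fell of 10). Their camera adjusted p ran from 0.0875 to 0.73. Slc5a7, the choline transporter of cholinergic neurons, changed by -1.84, and the red cell anion exchanger gene Slc4a1 by 1.59.

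In limma's test 9818 of 24511 genes differed between NG and IG (4817 higher in NG, 5001 lower), and 4470 of them by at least 2-fold. The authors' deposited table called 7331 (3515 higher in NG, 3816 lower), of which 7304 were among the limma calls, all in the same direction. Without IG A the count was 6252 and without IG B 6316.

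The comparison of TG with NG sets injured cells with hydrogen against injured cells without, as labelled. The lists of immediate early genes, cytokines, general neuron markers, spinal excitatory and inhibitory neurons, synaptic vesicles and the oligodendrocyte lineage were higher in TG, while that of motor and cholinergic neurons was not called. Muscle, connective tissue, endothelial, cell cycle and NADPH oxidase genes were lower in TG. Cxcl2, a neutrophil-attracting chemokine gene (chromosome 5, 90903871 to 90905938), rose most among the named genes, with 376 ± 37.5 in TG and 3.98 ± 2.89 in NG (log2 fold change 6.37, SE 0.36, limma adjusted p = 3.2e-06), higher in TG by 101-fold with a counting interval of 48.8 to 252. Il6 stood at 161 ± 16.6 in TG and 2.18 ± 0.330 in NG (log2 fold change 5.67, SE 0.23), higher in TG by 75.9-fold with a counting interval of 29.4 to 280. Col1a1, the main chain of fibrillar collagen, stood at 4301 ± 13.8 in TG and 34870 ± 3955 in NG (log2 fold change -3.01, SE 0.10, limma adjusted p = 4.1e-07).

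Immediate early genes rose in TG in 13 of 14 cases, also when adjusted over the list alone, with a median of 1.58 (camera adjusted p = 9.12e-07, and adjusted p = 0.227 with an estimated correlation). Among cytokines and NF-kB targets 12 of 15 rose and none fell (13 rose when adjusted over the list alone; median 2.67; camera adjusted p = 6.21e-06, and adjusted p = 0.085 with an estimated correlation). Axon injury and regeneration genes rose in 9 of 10 cases, also when adjusted over the list alone (camera adjusted p = 5.05e-05, and adjusted p = 0.085 with an estimated correlation), with Atf3 at 1137 ± 14.1 in TG and 104 ± 17.7 in NG. All 16 general neuron markers rose by either adjustment (median 1.19; camera adjusted p = 1.55e-07, and adjusted p = 0.085 with an estimated correlation). Syt1, a calcium sensor of synaptic vesicles, stood at 2351 ± 168 in TG and 499 ± 80.4 in NG (log2 fold change 2.24, SE 0.12, limma adjusted p = 2.2e-06). Of 10 excitatory and inhibitory neuron genes 9 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 6.17e-05, and adjusted p = 0.085 with an estimated correlation), with the GABA synthesis gene Gad2 at 1722 ± 8.50 in TG and 238 ± 25.5 in NG. Synaptic vesicle genes rose in 11 of 12 cases, also when adjusted over the list alone (camera adjusted p = 1.07e-06, and adjusted p = 0.0915 with an estimated correlation). All 14 receptor and channel genes rose by either adjustment (camera adjusted p = 6.81e-08, and adjusted p = 0.085 with an estimated correlation). In the oligodendrocyte list 10 of 12 rose and 1 fell, also when adjusted over the list alone (median 1.10; camera adjusted p = 1.84e-04, and adjusted p = 0.121 with an estimated correlation), with the tight junction gene of myelin Cldn11 at 40890 ± 543 in TG and 13160 ± 166 in NG. Cholesterol synthesis genes rose in 9 of 12 cases (10 when adjusted over the list alone; camera adjusted p = 5.00e-04, and adjusted p = 0.109 with an estimated correlation).

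Fibroblast and meningeal markers fell in TG in 11 of 12 cases, also when adjusted over the list alone, with a median of -2.39 (camera adjusted p = 1.63e-06, and adjusted p = 0.085 with an estimated correlation). Skeletal muscle genes fell in 6 of 7 cases by either adjustment (median -2.74; camera adjusted p = 2.86e-04, and adjusted p = 0.0915 with an estimated correlation), and Mylpf, a myosin light chain gene, stood at 2213 ± 197 in TG and 21000 ± 27.8 in NG. Endothelial markers fell in 6 of 9 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.00606, and adjusted p = 0.124 with an estimated correlation). All 12 cell cycle genes fell by either adjustment (median -2.35; camera adjusted p = 6.81e-08, and adjusted p = 0.085 with an estimated correlation), with the topoisomerase gene Top2a at 295 ± 15.3 in TG and 1492 ± 109 in NG. All 7 NADPH oxidase genes fell by either adjustment (median -2.21; camera adjusted p = 1.88e-05, and adjusted p = 0.085 with an estimated correlation). Cybb, the catalytic subunit, stood at 113 ± 13.1 in TG and 1129 ± 217 in NG (log2 fold change -3.30, SE 0.15, limma adjusted p = 1.3e-06). Microglia and macrophage markers fell in 8 of 14 cases and rose in 2, also when adjusted over the list alone, without a list call (camera adjusted p = 0.12, and adjusted p = 0.236 with an estimated correlation). Interferon-stimulated genes fell in 11 of 12 cases and rose in 1 by either adjustment (camera adjusted p = 7.18e-04, and adjusted p = 0.121 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases, also when adjusted over the list alone (median -1.54; camera adjusted p = 3.57e-05, and adjusted p = 0.227 with an estimated correlation), and these transcripts made up 17.2% and 14.2% of reads in the NG libraries.

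After Cxcl2, the highest named genes in TG were Cxcl1, Pkd1l2, Casr and Kcnk9. Casr encodes the calcium-sensing receptor and Kcnk9 a potassium leak channel, and their log2 fold changes were 4.35 and 4.01. The lowest were Cfd, Cd209b, Ces1d, Adig and Cyp2e1. Cfd was lower in TG by 189-fold with a counting interval of 136 to 270. Cd209b, a lectin gene of macrophages, had 2 reads in TG and was lower there by 223-fold with a counting interval of 61.3 to 1850. No call by camera with the preset correlation was made for motor and cholinergic neurons (2 rose, 4 fell of 7), astrocytes (7 rose, 1 fell of 12), microglia and macrophages (2 rose, 8 fell of 14), Schwann cells (1 rose, 5 fell of 8), ependymal cells (5 rose, 1 fell of 6), red blood cells (4 rose, 1 fell of 6), Nrf2 and antioxidant genes (4 rose, 4 fell of 14), apoptosis and p53 targets (2 rose, 5 fell of 14), endoplasmic reticulum stress (3 rose, 4 fell of 12), heat shock (6 rose, 2 fell of 10), reactive astrocytes (3 rose, 4 fell of 8), glial scar proteoglycans (6 rose, 3 fell of 12), nuclear oxidative phosphorylation genes (2 rose, 9 fell of 18), hypoxia and glycolysis (4 rose, 4 fell of 15), autophagy and lysosome (4 of 12 rose) and the mRNA methylation machinery (3 rose, 1 fell of 10). Of these, astrocytes and heat shock were called higher and Schwann cells lower after GC and length correction (adjusted p = 0.0154, 0.0294 and 0.0187), and astrocytes and heat shock also with a term for the deeper or shallower library (adjusted p = 0.0397 for both). Over all the lists without a call the camera adjusted p ran from 0.0773 to 0.853. Gpx1, a peroxide-reducing enzyme gene, stood at 3407 ± 189 in TG and 9078 ± 539.9 in NG. Fto, an mRNA demethylase gene, stood at 2661 ± 12.9 in TG and 1487 ± 16.8 in NG.

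In limma's test 11101 genes differed between TG and NG (5433 higher in TG, 5668 lower), 5983 of them by at least 2-fold. The authors' deposited table called 8905 (4440 higher in TG, 4465 lower), of which 8881 were among the limma calls, in the same direction. After GC and length correction 60.1% of calls were higher in TG, against 48.9% without it.

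The comparison of TG with IG sets injured cells with hydrogen against cells labelled as untreated. Synaptic, channel and spinal excitatory and inhibitory neuron genes were modestly higher in TG, as were 6 of 16 general neuron markers, while motor and cholinergic neuron genes were lower. Genes of liver, peripheral nerve, connective tissue and the cell cycle were lower in TG, as was the list of reactive astrocyte genes. The liver gene Alb, which encodes serum albumin (chromosome 5, 90460897 to 90476602), stood at 4.86 ± 1.19 in TG and 11760 ± 588 in IG (log2 fold change -10.98, SE 0.19, limma adjusted p = 1e-07), lower in TG by 2510-fold with a counting interval of 1360 to 5240. Hoxa10, a patterning gene of the posterior body axis (chromosome 6, 52231197 to 52240854), stood at 467 ± 21.6 in TG and 122 ± 5.56 in IG (log2 fold change 1.93, SE 0.11, limma adjusted p = 4.8e-05).

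Of 16 general neuron markers 6 rose in TG and none fell (11 rose when adjusted over the list alone), with a median of 0.33 (camera adjusted p = 1.68e-04, and adjusted p = 0.0992 with an estimated correlation). Excitatory and inhibitory neuron genes rose in 6 of 10 cases (7 when adjusted over the list alone; camera adjusted p = 0.00143, and adjusted p = 0.104 with an estimated correlation), with Gad2 at 1722 ± 8.50 in TG and 974 ± 33.8 in IG. Synaptic vesicle genes rose in 9 of 12 cases (12 when adjusted over the list alone; camera adjusted p = 1.46e-06, and adjusted p = 0.104 with an estimated correlation), and receptor and channel genes in 9 of 14 (11 when adjusted over the list alone; camera adjusted p = 6.12e-07, and adjusted p = 0.0914 with an estimated correlation). Grin2b, an NMDA receptor subunit gene, changed by 0.89. Axon injury and regeneration genes rose in 4 of 10 cases (6 when adjusted over the list alone; camera adjusted p = 0.0186, and adjusted p = 0.157 with an estimated correlation), a call lost without IG A and without IG B. Their median was 0.38 with all libraries, and 0.33 and 0.40 in those fits. Skeletal muscle genes rose in 4 of 7 cases, also when adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.182 with an estimated correlation), a call lost without TG A, without TG B and with a term for the deeper or shallower library. Their median was 0.49 in the main fit, and 0.50, 0.48 and 0.49 in those fits. Nuclear oxidative phosphorylation genes were called higher as a list with 1 of 18 members passing (none when adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.157 with an estimated correlation), a call lost with total read scaling. That scaling took the median from 0.14 to 0.07.

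All 12 fibroblast and meningeal markers fell in TG by either adjustment, over all genes or adjusted over the list alone, with a median of -1.12 (camera adjusted p = 3.42e-10, and adjusted p = 0.0914 with an estimated correlation). Schwann cell genes fell in 7 of 8 cases by either adjustment (median -1.45; camera adjusted p = 9.63e-07, and adjusted p = 0.0914 with an estimated correlation). In the motor and cholinergic neuron list 5 of 7 fell (7 when adjusted over the list alone; camera adjusted p = 2.78e-06, and adjusted p = 0.0914 with an estimated correlation). The members Prph and Isl2 are also genes of peripheral sensory neurons, and they changed by -1.29 and -2.52. Reactive astrocyte genes fell in 7 of 8 cases (8 when adjusted over the list alone; median -1.01; camera adjusted p = 2.41e-07, and adjusted p = 0.104 with an estimated correlation). Vim, an intermediate filament gene, stood at 5297 ± 126 in TG and 11660 ± 162 in IG. The lipocalin gene Lcn2 stood at 532 ± 39.5 in TG and 1427 ± 108 in IG. The list of general astrocyte markers was not called in this comparison (1 rose and 2 fell of 12). Which cell type accounts for the fall of the reactive astrocyte list was not tested. Proteoglycan genes fell in 7 of 12 cases by either adjustment (camera adjusted p = 1.96e-04, and adjusted p = 0.0992 with an estimated correlation). Cell cycle genes fell in 11 of 12 cases (12 when adjusted over the list alone; median -0.86; camera adjusted p = 5.07e-09, and adjusted p = 0.0914 with an estimated correlation), with Top2a at -1.12. NADPH oxidase genes fell in 6 of 7 cases by either adjustment (camera adjusted p = 1.68e-04, and adjusted p = 0.0992 with an estimated correlation), with Cybb at 113 ± 13.1 in TG and 315 ± 15.6 in IG. Beside them, 3 of 14 microglia and macrophage markers fell, among them Ptprc (6 when adjusted over the list alone; camera adjusted p = 0.0112, and adjusted p = 0.149 with an estimated correlation).

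The highest named genes in TG were Rpl17-ps5, Slc17a7, Hoxa10, Hoxc10 and Hoxd9. Rpl17-ps5 had 0 reads in IG and was at least 186-fold higher in TG, with the same uncertainty over shared reads. Slc17a7, a vesicular glutamate transporter gene, stood at 214 ± 2.39 in TG and 50.1 ± 6.26 in IG. The lowest were Alb, Ahsg, Mat1a, Fgg and Apoa2. Mat1a had 0 reads in TG and was at least 553-fold lower there, and Apoa2 had 1 read and was lower by 1180-fold with a counting interval of 211 to 46500. Without a call by camera with the preset correlation were astrocytes (1 rose, 2 fell of 12), oligodendrocytes (2 rose, 2 fell of 12), endothelial cells (2 of 9 fell), ependymal cells (0 of 6 passed), red blood cells (1 of 6 fell), immediate early genes (3 rose, 3 fell of 14), Nrf2 and antioxidant genes (2 of 14 fell), apoptosis and p53 targets (1 of 14 fell), endoplasmic reticulum stress (2 rose, 2 fell of 12), heat shock (3 of 10 fell), cytokines and NF-kB targets (3 of 15 fell), interferon-stimulated genes (1 of 12 fell), mitochondrially encoded genes (0 of 13 passed), hypoxia and glycolysis (1 rose, 3 fell of 15), autophagy and lysosome (1 of 12 fell), cholesterol synthesis (0 of 12 passed) and the mRNA methylation machinery (0 of 10 passed). Of these, heat shock was called lower with total read scaling, with the depth term, and without NG A or NG B (adjusted p = 0.038, 0.0491, 0.0396 and 0.037). Over all the lists without a call the camera adjusted p ran from 0.0593 to 0.957. Tnf, which fell, stood at 40.7 ± 8.62 in TG and 141 ± 27.3 in IG. Hspa1a, which also fell, stood at 175 ± 8.82 in TG and 510.1 ± 94.0 in IG.

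**Figure D2:**
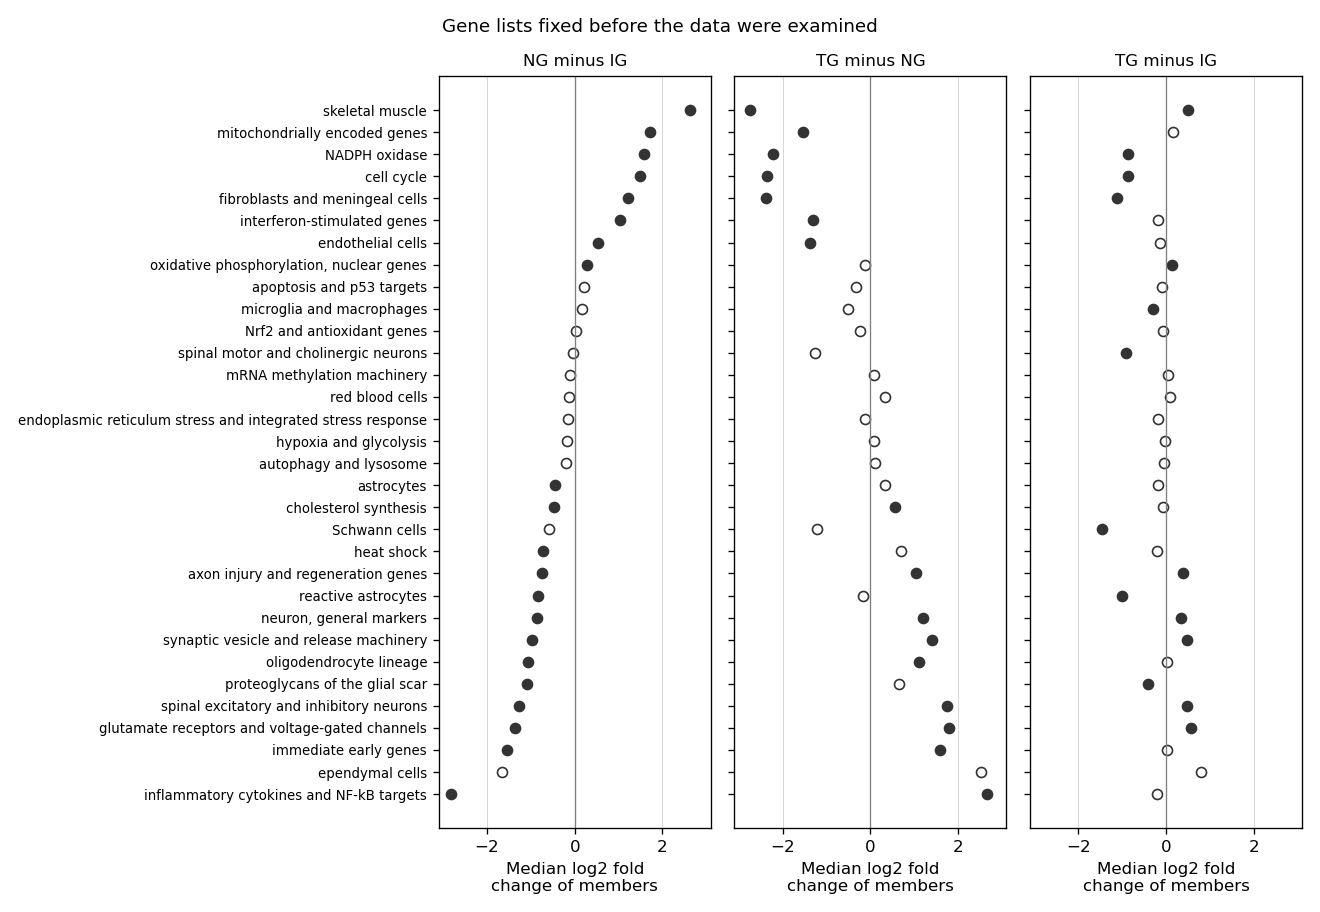
Median log2 fold change of the members of each of the 32 fixed gene lists in each comparison, with filled points for lists called by camera at a preset correlation of 0.01 and open points for the others. Cytokine and immediate early genes lie at -2.82 and -1.54 in NG minus IG and at 2.67 and 1.58 in TG minus NG, and at -0.22 and 0.02 in TG minus IG.

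In limma's test 2779 genes differed between TG and IG (1020 higher in TG, 1759 lower), 921 of them by at least 2-fold. With total read scaling 24.4% of calls were higher in TG and after GC and length correction 60.5%, against 36.7%. The authors' deposited table called 2642 (1057 higher in TG, 1585 lower), of which 2329 were among the limma calls, in the same direction. The count fell whichever library was left out, those of NG included, with 2 residual degrees of freedom instead of 3. It was 76 without IG A, 81 without IG B, 1012 without NG A, 944 without NG B, 2 without TG A and 0 without TG B. With all 6 libraries it was 1318 with no trend in the prior variance, 5862 with a term for the deeper or shallower library and 5660 after GC and length correction.

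Set against both other groups, TG lay on the IG side of NG for most genes. Of the 9818 genes that differed between NG and IG, 97.05% had a TG minus NG difference of the opposite sign, against 78.2% in simulated unchanged groups that share the NG libraries, over as many genes picked by their own simulated NG minus IG difference. In this set 4257 genes rose from IG to NG and fell from NG to TG, where independent lists would share 1114, and 4171 did the reverse, where they would share 1108. The values for independent lists leave out the shared NG libraries and the simulated value leaves out the effects, so neither excess measures a shared effect. Across 24511 genes, which are not independent replicates, the correlation of the paired fold changes was -0.768 against a simulated -0.5. Their covariance was -0.925 against -0.0725, a difference of -0.852. With 1 NG library in each contrast, so that none was in both, the correlation was -0.636 (NG A less IG) and -0.631 (NG B less IG), against a simulated 0.001. The split removes only noise particular to a library. Anything that both NG libraries share, such as transcripts of other tissues, stays in both contrasts, and the simulated libraries varied independently. Immediate early and cytokine genes such as Fosb and Il6, and neuronal genes such as Gad2 and Slc6a5, fell in NG against IG and rose in TG against NG. In a comparison added after the data were seen, for 38.8% of the 9818 genes TG lay on the NG side of IG, against 78.2% in simulated unchanged groups that share the IG libraries, picked in the same way. TG differed from IG toward NG in 636 of these genes and away from NG in 1500. Cell cycle, fibroblast and NADPH oxidase genes such as Top2a, Col1a2 and Cybb were among those that lay beyond IG.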

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

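Alternatives for the scaling (upper quartile, total reads), the prior variance, voom weights, the depth term, the GC and length correction and the authors' table as an alternative to limma were chosen after seeing the data, as were the counts of lists beyond random ones matched in 10 bins, the share of genes with TG on the NG side of IG and the fits and the split of NG for both shares, and the others were planned. The planned edgeR and DESeq2 fits and the filterByExpr filter were not run, since the deposited columns are means and not reads, although the recovered reads would have allowed them. No paired analysis was possible because the deposited means carry no replicate numbers. A block on the deeper or shallower library of each group, which may or may not match those numbers, gave 12027, 13034 and 5862 calls in NG against IG, TG against NG and TG against IG. Without 1 library at a time, where the lone library of a group is assumed to vary like the other groups and 1 residual degree of freedom is lost, the count for NG against IG was 6252 to 7566, that for TG against NG 7776 to 9541, and that for TG against IG 0 to 1012. The 0 arose without TG B, while 2 genes passed without TG A, and 76 and 81 passed without IG A and B. With no trend in the prior variance the count for TG against IG was 1318, and after GC and length correction 5660. The cause was not tested without the trend or after the correction, and the depth term removes a difference that the groups share. At least a 2-fold change left 4470, 5983 and 921 calls in NG against IG, TG against NG and TG against IG, and an adjusted p under 0.01 left 1266 in the last, by their construction. With an estimated correlation camera called 0 of the fixed lists in each comparison, against 21, 16 and 15, and it also called 0 of 5 moved lists in simulated data. Since the simulated genes varied independently, that does not show which of the settings is right for the real lists. After GC and length correction 4 of 286 named results changed sign, all in TG against NG, with log2 fold changes of 0.02 for Fabp7, 0.09 for Cox7c, 0.05 for Ndufa4 and 0.02 for Sdhb (the cause was not tested). No other named result changed sign in any alternative. Over the genes called in each alternative fit, the share of opposite signs was 96.01% (depth term) to 98.57% (authors' p over genes with a mean of at least 50), and that of TG on the NG side of IG 33.54% to 44.57% (without IG B). Apart from the 2-fold limit the count for TG against NG stayed within 1.5-fold, as did the count of lists apart from the estimated correlation. Other scalings moved the median of all genes by under 0.1 on the log2 scale. Genes near the floor of 3 reads limit what depth can show, and folds there are bounds or have wide intervals.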

Other observations

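The lists of immediate early, cytokine, microglia, fibroblast, Schwann cell and skeletal muscle genes were planned. The limma test was planned for normalised values per library, and its use on recovered reads was not. The added lists, the Hox comparison, the GC and length correction and the tests of each explanation were chosen after the results had been seen, and the added lists were written after the genes with the largest changes were known. Members of the second lists and of the sensory neuron list were chosen without their values having been looked at.

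Peripheral sensory neuron genes were low in TG. Of 10 genes of dorsal root ganglion neurons 8 fell in TG against IG and 9 in TG against NG, with medians of -2.57 and -2.97 (camera adjusted p = 1.25e-09 and 2.68e-06, and adjusted p = 0.0219 and 0.0333 with an estimated correlation). In NG against IG 4 rose, with a median of 0.78 (camera adjusted p = 0.00471, and adjusted p = 0.0722 with an estimated correlation). Scn10a, the sodium channel of pain-sensing neurons, stood at 6.25 and 6.35 CPM in the IG libraries, 13.1 and 13.6 in NG, and 0.586 and 0.476 in TG. The lists of lung epithelium and adrenal cortex were called in no comparison (camera adjusted p of 0.299 or more). Lists for other tissues gave these calls. Hepatocyte genes fell in 12 of 14 cases and rose in 1 in NG against IG, fell in 4 and rose in 2 in TG against NG, and fell in all 14 in TG against IG. The second liver list fell in 12, 2 and 12 of 12 cases in the same comparisons. Adipocyte genes rose in 10 of 10 cases in NG against IG, fell in 10 in TG against NG, and rose in 1 and fell in 3 in TG against IG, and the second fat list gave 9 rises, 9 falls and 1 fall of 10. Smooth muscle genes rose in 8 of 8 cases, fell in 8, and rose in 1 and fell in 4. The second muscle list rose in 9 of 10 cases, fell in 10, and rose in 4 and fell in 3. Within NG the steroid synthesis gene Cyp11a1 stood at 1.1 CPM in library A and 41.3 in library B, and Hsd3b1 at 0.0997 and 13.1.

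The Mbp transcript ranked first in the IG and TG libraries and second in both NG libraries, at 40800 to 73400 CPM, in samples labelled as cultured neurons. Xist, transcribed from the inactive X chromosome of females, stood at 9.65 and 9.59 CPM in IG, 27 and 22.5 in NG and 28.1 and 24.8 in TG (limma adjusted p = 5.15e-05 for NG against IG and 2.39e-04 for TG against IG). The Y-linked gene Ddx3y stood at 76.2 to 102 CPM in the 6 libraries (limma adjusted p = 0.649 for NG against IG). The beta-globin gene Hbb-bt stood at 106 and 159 CPM in NG against 795 to 1240 in IG and TG, while Hbb-bs stood at 5880 to 9600 CPM in the 6 libraries. Rpl17, the parent gene of Rpl17-ps5, stood at 902 and 931 CPM in NG and at 372 to 398 in the others. Rpl17-ps5 itself stood at 0 CPM in both IG libraries, 114 and 131 in NG and 13.3 and 13.7 in TG. A fixed share of Rpl17 reads would have left reads in IG too, so these values argue against it as the source of the differences from IG.

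Immediate early and cytokine genes, which injury and cell stress are known to induce, were lower in the libraries labelled injured than in those labelled control. GC content or transcript length bias is argued against, since 28 of the 29 members were called lower in NG after correction, against 26 before, and the median went from -1.93 to -2.09. More macrophages and microglia in the IG libraries is argued against too, since 2 of 14 markers were called higher in IG and 5 higher in NG. If the labels of the IG and NG groups were exchanged, TG, labelled injured, would also lie above NG, and 25 of the 29 members were called higher in TG than in NG, with a median of 0.06 below IG at the same time. These calls were known when the criterion was set and use the same NG libraries, so they add no separate support. An exchange of labels could give this direction, but an injury that lowered these genes and hydrogen that raised them would give the same order, and neither was tested. The authors gave their ratios as IG over NG, TG over NG and TG over IG. NG was thus the denominator wherever it stood, as a control often is, while IG, labelled control, was the numerator against it. That choice alone does not settle which labels are right.

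Transcripts of other tissues were found in the IG and NG libraries, with summed levels of 1460 and 1390 CPM of hepatocyte genes in IG A and B and 1800 and 1750 CPM of adipocyte genes in NG A and B, but 3.74 and 72.6 CPM of adrenal cortex genes in NG A and B. RNA from liver in the IG libraries is a candidate source of the first: all 12 members of a second liver list, none of them named before, were called higher in IG than in NG, with Alb at 669 and 621 CPM in IG and at most 1.94 CPM elsewhere. RNA from muscle and fat in the NG libraries is a candidate source of the second, with 18 of 20 members of second lists called higher in NG, Cfd at 166 CPM in both NG libraries and the smooth muscle gene Acta2 at 524 and 514 CPM. The elastin gene Eln stood at 4480 and 6670 CPM in NG, against 135 and 172 in IG and 122 and 142 in TG. Its source was not tested, and skeletal muscle and fat need not be the only tissues involved. In the IG libraries 7 of the 10 members of the second fat list and at least 9 of the 10 of the second muscle list also reached 5 CPM, as did 7 and at least 8 in TG. The first skeletal muscle list summed to 633 and 630 CPM in TG against 469 and 488 in IG and 3980 and 4290 in NG. The second muscle list summed to 244 and 249 CPM in TG, 281 and 275 in IG and 1210 and 1230 in NG. Whether a lower share of cord tissue in NG was the whole cause of the fall of neural markers was not decided. Fibroblast markers exceeded Schwann cell markers by 1.63 in mean log2 fold change (SE 0.38), but added tissue that carries its own fibroblasts would give such a difference too.

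Of 10 posterior Hox genes (paralog groups 9 to 11) 5 were called higher in TG than in IG, 2 of them among the 7 not named by size, as were 4 of the 15 genes of groups 4 to 8. A more caudal level of the cord in the TG libraries may account for this: without the 3 genes named by size, which prompted the pattern, the median log2 fold change of the 7 other genes of paralog groups 9 to 11 exceeded that of the 15 genes of groups 4 to 8 by 0.56 (0.97 against 0.41; two-sided permutation p = 0.017 over 100000 regroupings of genes, which are not independent). In NG against IG the genes of groups 9 to 11 went both ways, with 4 called higher and 3 lower. GC content or transcript length bias is argued against, since all 5 genes of groups 9 to 11 called higher in TG stayed called after correction. Without IG A or IG B 3 of the 5 stayed called, and without TG A or TG B 0 did.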
